A study of Homo sapiens with 42 samples.

How the data were processed

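Peripheral blood mononuclear cells of 4 donors were cultured with interferon gamma, LPS, PMA with ionomycin, or DMSO alone, for 1 h or 6 h, and at 6 h also with a Golgi inhibitor. Per the labels, libraries were made with the SureCell WTA 3′ kit on the ddSEQ droplet system, and each library came from 1 donor under 1 condition. Cells of a donor were cultured apart for each condition, so p-values measure the spread between donors and cultures together. The 42 libraries were assigned to 12 groups from their labels.

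The deposited values were whole counts per gene and cell, without scaling, for 19222 genes and 23754 cells. Their sum in every cell equalled the total in the deposited cell table, whose entries name the library of each cell. The submitters' processing notes name STAR 2.5.2b, Seurat and the genome build hg19, and they do not say how cells were called or which cells were removed. The lowest cell held 201 genes and 247 counts. No mitochondrially encoded gene was in the matrix, so the share of their reads could not be used to judge cells. The deposited table named no cell type. All deposited cells were used, and 22 sex-linked genes were taken out before any other step. No doublet caller was run, and fits were repeated without the 5% of cells with most counts in each library. In monocytes this was not run for LPS among libraries with the inhibitor, nor for the difference of the LPS response with the inhibitor.

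Cells were clustered within each group with scanpy 1.11.5 on Python 3.11.15, with 1500 variable genes chosen across replicates, counts scaled to 10000 per cell, 20 principal components, 15 neighbours and Leiden resolution 1. Each cluster was scored by the log2 ratio of its mean marker level to that of the group, for marker lists of monocytes, T cells, NK cells and B cells fixed before the data were examined. Clusters led by monocyte markers were pooled and clustered again. A cluster took the name of its highest score if at least 3 markers of the class held 3 counts, and if its 10 leading genes (pseudocount 20 CPM) held no more markers of another class. A cluster was left unnamed if it was shallow with no marker of its own among those genes, held under 10 cells, mixed monocyte and lymphocyte markers, or led with at least 3 of 8 dendritic cell genes among 15 leading genes. Of 177 clusters 155 were named, and 830 cells (3.49%) were not. The naming rule was changed after clusters were seen. Platelet and plasmacytoid dendritic cell lists no longer competed for a name, the second clustering and the dendritic cell genes were added, and NK cells were merged with cytotoxic T cells, because clusters held both. Some genes that named clusters also belong to gene lists, so those lists were also counted without them.

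Counts were summed per library and class, and a library entered a class with at least 10 cells. This left out LPS_1h replicate 4 among monocytes, with 3 cells of 138. Sums ran from 39623 to 850316 counts in monocytes, 54394 to 2572143 in T cells, 10475 to 1458422 in NK and cytotoxic T cells and 18166 to 544408 in B cells. Bounds from 3 counts cover counting error only.

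Each class was fitted with edgeR 4.0.16 on R 4.3.3 (TMM scaling, filterByExpr by group, quasi-likelihood F-tests) in 1 model with a mean for each of 12 groups. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called. The filter left 6397 genes in monocytes, 10476 in T cells, 8064 in NK and cytotoxic T cells and 6069 in B cells. Each stimulus was compared with the control of the same time, the inhibitor alone with the 6 h control, and responses with each other as differences of differences. Of these comparisons 26 were fixed before the data were examined, with their tests and alternatives. Another 9 were added afterwards: stimuli among libraries with the inhibitor, and the 6 h against the 1 h control.

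Gene lists (28 fixed before the data were examined, 26 with a measured gene) were tested by camera from limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over lists and comparisons. Camera with an estimated correlation and fry were run beside it. Named genes followed a rule fixed in advance: among called genes whose stimulated libraries all lay on one side of all control libraries, the 12 largest rises and 6 largest falls, plus list members. Exceptions are given where they occur. The share of monocytes per library was compared by exact permutation of all library labels, adjusted over 6 tests.

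Replicate numbers are donor numbers in the labels. Residuals of group means correlated more between libraries of a donor than between other libraries, with mean r of 0.056 against -0.021 in monocytes, 0.107 against -0.039 in T cells, 0.058 against -0.021 in NK and cytotoxic T cells and 0.05 against -0.017 in B cells. The model planned in advance did not hold the donor, and every fit was repeated with it.

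Counts were simulated from each gene's mean over all libraries of the class and its fitted spread. They held no donor effect and were run through the same steps. Changes up and down were set in LPS at 6 h against the 6 h control. In monocytes 86 genes changed 2-fold and 94 changed 4-fold of 5641, and in T cells 93 and 97 of 9996. Of 4-fold changes 21.3% were recovered in monocytes and 71.1% in T cells, and of 2-fold changes 3.5% and 24.7%, with 0 and 2 false calls. DESeq2 1.42.0 recovered 29.8% and 71.1% of 4-fold changes, with 1 and 5 false calls. In this setting small changes were mostly missed, above all in monocytes. Several real comparisons called far more genes, so these shares and false calls do not carry over to their counts.

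DESeq2 changed size factors, spread estimates and test together, and the other alternatives changed 1 choice at a time. The alternatives were median-of-ratios size factors (RLE), DESeq2, no filter beyond 1 count, only the groups compared and the donor in the model. Further alternatives were donor 4 left out, at least 30 cells, no cells with most counts, and each library left out in turn. For monocyte shares they were the 4 named classes as denominator, log odds, a sign-flip test within donors, and clustering again without 7318 genes called after a stimulus, the last chosen after the data were seen. RLE moved the median change of all genes by over 0.1 (log2) from that under TMM in 14 of 35 comparisons, by -0.47 for PMA/ionomycin at 6 h in monocytes and at most 0.241 upward.

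Every way of splitting the libraries compared into groups of the same sizes was also fitted. For differences of differences the stimulus labels were first shuffled within each arm (40 draws). After those results were seen, a second scheme exchanged whole donor pairs of stimulated and control library between the arms, and both are reported. Values of some genes, sex-linked genes among them, are not reported.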

Results

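The samples were peripheral blood mononuclear cells from 4 donors, given as replicates 1 to 4, stimulated in culture and profiled by droplet-based 3′ single-cell RNA sequencing. Cells received interferon gamma, the bacterial lipopolysaccharide LPS, or PMA with ionomycin, a pair of chemicals that triggers T cell activation through protein kinase C and calcium. Each stimulus was given for 1 h and 6 h, with DMSO controls at both times. At 6 h each arm was also run with GolgiPlug, an inhibitor of protein transport through the Golgi. The 42 libraries formed 12 groups. Both controls, LPS and PMA/ionomycin held 4 libraries at each time, and the interferon gamma groups and all groups with the inhibitor held 3, without replicate 4. Library totals ran from 86228 to 4728793 counts, and the median over all 23754 cells was 2027 counts per cell. The interferon gamma libraries and the libraries with the inhibitor were deeper, with medians of 3685 to 11988 counts per cell and 1 exception at 2127, than the other libraries, with 521.5 to 3355. Comparisons of interferon gamma with the plain control, and of the inhibitor with no inhibitor, span this gap.

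Clusters were named as monocytes (2886 cells), T cells (14016), NK and cytotoxic T cells together (4005) or B cells (2017). Gene values below are counts scaled by the library's total over tested genes of the class times its TMM factor (CPM, mean ± SD over libraries). Log2 changes are given ± SE, with p adjusted over all genes tested in the class. The SE was worked back from the test, as the absolute log2 change over the square root of its F statistic. The factors were set within each class, so levels set beside each other across classes are approximate. Every gene named from a comparison with a control lay, in each stimulated library, beyond all control libraries on the same side, unless said otherwise. Where a group had no count of a gene, the fold is a lower bound set by 3 counts over that group. List results give the members that rose or fell among those measured and the adjusted p of the list test. A list call was also made with an estimated correlation between genes, and a call lost there is given with that p.

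Interferon gamma at 1 h raised its target genes and MHC class II genes in monocytes (n = 3 against 4). CXCL9, a chemokine that attracts T cells, was at least 227-fold higher (359 ± 273 CPM against no count in the controls). CCL8, another chemokine, rose by 6.99 ± 1.08 on the log2 scale, and CXCL10 by 4.60 ± 1.09. CISH and SOCS1, feedback inhibitors of cytokine receptors, rose by 4.92 ± 0.79 and 3.95 ± 0.87. CXCL8, a chemokine for neutrophils, fell by 4.66 ± 0.55, from 1428 ± 979 to 54.9 ± 30.2 CPM. Of 31 measured targets of interferon gamma, 14 rose and 17 did not pass (20 rose adjusted over the list alone, adjusted p = 1.11e-15). MHC class II genes, whose products present antigen to helper T cells, rose for 5 of 11 members (10 adjusted over the list alone, adjusted p = 2.08e-09). Of 30 genes of the type I interferon signature, 8 rose (13 adjusted over the list alone, adjusted p = 1.02e-07, and adjusted p = 0.211 with an estimated correlation). In all, 133 genes rose and 85 fell of 6397 tested. The count of 218 was 105 without IFN_1h replicate 1 and 670 when the model held only these groups, and CXCL10 did not pass without donor 4. The deeper libraries hold no control at 1 h, so this comparison could not be repeated among them.

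At 6 h of interferon gamma, monocytes (n = 3 against 4) had higher levels of interferon gamma targets and antigen presentation genes. UBD, a ubiquitin-like gene induced by cytokines, was at least 90.9-fold higher (497 ± 275 CPM against no count). CXCL11 rose by 7.15 ± 1.10, CXCL9 by 6.44 ± 1.02 and IDO1, an enzyme that degrades tryptophan, by 6.40 ± 0.79 on the log2 scale. GBP5, a guanylate-binding protein of cell defence, rose by 3.02 ± 0.59, and CD274, the checkpoint ligand PD-L1, by 4.19 ± 0.68. CX3CR1, a receptor of patrolling monocytes, was at least 27.5-fold lower and did not pass without IFN_6h replicate 1. Of the interferon gamma targets, 22 of 31 rose and 9 did not pass (26 adjusted over the list alone, adjusted p = 1.72e-31). MHC class II genes rose for 9 of 11 members (10 adjusted over the list alone, adjusted p = 1.87e-11), among them HLA-DRA by 2.37 ± 0.44 and CD74, the invariant chain, by 1.99 ± 0.40. Class I and antigen processing genes rose for 5 of 17 (10 adjusted over the list alone, adjusted p = 2.68e-08), and NF-kB feedback genes for 8 of 24 (11 adjusted over the list alone, with 2 that fell; adjusted p = 7.22e-08). In all, 219 genes rose and 186 fell, against 245 and 375 by DESeq2 and 391 and 232 with at least 30 cells per library.

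Both arms with the inhibitor came from the deeper libraries, so interferon gamma was also compared there, a comparison added after the data were seen (n = 3 against 3). In monocytes MHC class II genes rose for 9 of 11 members (10 adjusted over the list alone, adjusted p = 1.03e-31), with HLA-DRA at 2.53 ± 0.49 and HLA-DQA1 at 4.56 ± 0.75. IDO1 rose by 5.97 ± 0.92 and CD40, a receptor for T cell help, by 4.48 ± 0.63. The targets rose for 2 of 31 members (13 adjusted over the list alone, adjusted p = 2.83e-18, and unadjusted p = 0.000567 by camera with an estimated correlation). The total was 23 genes, against 405 for interferon gamma without the inhibitor, and UBD, CXCL11, CXCL9, GBP5, CD274 and CX3CR1 did not pass there. CXCL9 stood at a log2 change of 5.02 ± 1.20, GBP5 at 1.80 ± 0.66 and CD274 at 1.32 ± 0.80, and CXCL11 at 10.3 ± 9.12 CPM against no count. HLA-DRA and CD74 did not pass without ControlGolgiPlug_6h replicate 2, and DESeq2 did not call UBD or CXCL9 in the comparison without the inhibitor. Levels after interferon gamma differed between the deep groups themselves. IDO1 stood at 9011 ± 1262 CPM without and 779 ± 216 CPM with the inhibitor, and HLA-DRA at 12200 ± 2093 and 7675 ± 2567 CPM. Depth of the control and the inhibitor both differ between the comparisons, so in no class can a lost call be assigned to either.

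LPS, which monocytes sense through the receptor TLR4, raised inflammatory cytokines in monocytes within 1 h (n = 3 against 4). IL6, a fever-inducing cytokine, rose by 8.61 ± 1.28 on the log2 scale, from 4.76 ± 5.19 to 2212 ± 1231 CPM. TNF rose by 7.55 ± 0.74, CCL4, a chemokine, by 7.17 ± 1.21, and IL1B, the precursor of interleukin 1 beta, by 5.04 ± 0.73. NFKBIA, the inhibitor of NF-kB, rose by 2.68 ± 0.46 and CD83, an activation marker, by 3.63 ± 0.36. CCR1, a chemokine receptor, was at least 20.5-fold lower. Inflammatory cytokine genes rose for 12 of 27 members (15 adjusted over the list alone, with 2 that fell; adjusted p = 2.75e-25). NF-kB feedback genes rose for 12 of 24 (16 adjusted over the list alone, adjusted p = 8.39e-34), and immediate early genes, the first to answer a signal, for 13 of 31 (19 adjusted over the list alone, with 1 that fell; adjusted p = 1.28e-28). In all, 97 genes rose and 10 fell. The total of 107 was 64 without the 5% of cells with most counts.

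By 6 h of LPS (n = 4 against 4), genes of inflammation and of the type I interferon signature were higher in monocytes, and genes of monocyte identity were lower. IL1A was at least 819-fold higher, CCL20, a chemokine, at least 481-fold, IL12B, a subunit of interleukin 12, at least 274-fold, and CSF3, a growth factor of neutrophils, at least 195-fold, each against controls with no count. CCL3, a chemokine, rose by 9.91 ± 0.96 and IL6 by 8.17 ± 1.15 on the log2 scale. Of the inflammatory cytokine genes 25 of 27 rose (25 adjusted over the list alone, adjusted p = 4.51e-36), and of the NF-kB feedback genes 20 of 24 (20 adjusted over the list alone, with 1 that fell; adjusted p = 4.31e-30). The type I interferon signature rose for 23 of 30 members (28 adjusted over the list alone, adjusted p = 1.14e-19), including ISG15, a ubiquitin-like antiviral protein, by 4.31 ± 0.67 and MX1, an antiviral GTPase, by 2.76 ± 0.71. Monocyte identity genes fell for 11 of 24 members (13 adjusted over the list alone, adjusted p = 2.41e-10), and for 4 of 11 when the genes that named the clusters were left out. CD36, a scavenger receptor, was at least 29.8-fold lower, FGL2, a prothrombinase, at least 61.1-fold and ITGB2, an integrin chain, at least 17.5-fold. MHC class II genes fell for 4 of 11 (8 adjusted over the list alone, adjusted p = 0.00015, and adjusted p = 0.175 with an estimated correlation). In all, 487 genes rose and 479 fell (505 and 587 by DESeq2). DESeq2 did not call IL12B.

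The responses to LPS at 6 h and 1 h differed for 260 genes in monocytes, by the test of the difference (n = 4, 4, 3 and 4). IL10, an anti-inflammatory cytokine, had a response higher at 6 h by 5.85 ± 1.04 on the log2 scale, and ISG20, an antiviral exonuclease, by 3.54 ± 0.69. JUND, a transcription factor of the AP-1 family, had a response lower at 6 h than at 1 h, by -2.82 ± 0.46. Class II genes were lower for 5 of 11 members (10 adjusted over the list alone, adjusted p = 2.19e-09), with HLA-DPA1 at -3.98 ± 0.74. Inflammatory genes were higher at 6 h for 8 of 27 (12 adjusted over the list alone, with 1 lower; adjusted p = 5.32e-07, and adjusted p = 0.0665 with an estimated correlation). Without the 5% of cells with most counts 112 genes passed and HLA-DPA1 did not.

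PMA/ionomycin at 1 h raised immediate early genes in the monocyte class (n = 4 against 4). EGR3, a zinc finger transcription factor, rose by 7.45 ± 0.66 on the log2 scale, and the nuclear receptors NR4A3 and NR4A1 by 6.07 ± 0.74 and 5.60 ± 0.79. FOS rose by 4.15 ± 0.64, DUSP2, a phosphatase that restrains MAP kinases, by 5.21 ± 0.53 and TNF by 4.56 ± 0.65. Immediate early genes rose for 19 of 31 members (25 adjusted over the list alone, with 1 that fell; adjusted p = 2.39e-66). Genes of lymphocyte cytokines rose for 9 of 17 (12 adjusted over the list alone, adjusted p = 1.13e-20), and for 6 of 13 without the genes that named clusters. IFNG, the gene of interferon gamma, was among them, with 1385 ± 1069 CPM against 4.47 ± 3.05, beside 2013 ± 717 CPM in T cells of the same group. RNA from other cells was not tested at 1 h. In all, 94 genes rose and 28 fell. The total of 122 was 70 with donor 4 left out and 229 when only these groups were modelled.

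At 6 h of PMA/ionomycin (n = 4 against 4), 29 of 31 immediate early genes were higher in the monocyte class (30 adjusted over the list alone, with 1 that fell; adjusted p = 1.02e-21). EGR1, an early transcription factor, was at least 509.8-fold higher, and INHBA, a subunit of activin, at least 199-fold. CXCL8 rose by 4.73 ± 0.46, and 16 of 27 inflammatory genes rose while 1 fell (18 and 1 adjusted over the list alone, adjusted p = 8.5e-08). Ribosome biogenesis and MYC target genes rose for 10 of 19 (13 adjusted over the list alone, adjusted p = 1.76e-05), and apoptosis and p53 genes for 8 of 11 (8 adjusted over the list alone, adjusted p = 4.39e-05). Monocyte identity genes fell for 13 of 24 while 3 rose (15 and 3 adjusted over the list alone, adjusted p = 3.71e-07), or 5 and 3 of 11 without the genes that named clusters. THBS1, an adhesive glycoprotein, and FUCA1, a lysosomal fucosidase, were at least 1429-fold and 256-fold lower. Lymphocyte cytokines rose for 13 of 17 and fell for 2 (13 and 2 adjusted over the list alone, adjusted p = 1.2e-07), or 11 and 2 of 13 without the naming genes. IL2, a growth factor that T cells make, stood at 2683 ± 457 CPM against no count in the controls, beside 33960 ± 12190 CPM in T cells of the same group. In all, 974 genes rose and 714 fell, but 694 rose and 1231 fell with median-of-ratios (RLE) factors, so which side held more genes depended on the scaling.

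In T cells interferon gamma raised some of its target genes. At 1 h (n = 3 against 4), GBP5 rose by 3.44 ± 0.53 and IRF1, a transcription factor of the interferon response, by 1.89 ± 0.28 on the log2 scale. The targets rose for 6 of 23 members (8 adjusted over the list alone, with 1 that fell; adjusted p = 2.46e-06, and adjusted p = 0.0866 with an estimated correlation). At 6 h GBP5 rose by 3.86 ± 0.52 and GBP1 by 2.79 ± 0.50. The targets then rose for 12 of 23 (15 adjusted over the list alone, adjusted p = 2.93e-17), and class I and antigen processing genes for 10 of 17 (10 adjusted over the list alone, adjusted p = 1.01e-11). PSMB9, an immunoproteasome subunit, rose by 1.66 ± 0.24 and TAP1, the peptide transporter, by 1.25 ± 0.20. In all, 324 genes rose and 291 fell at 1 h, and 517 rose and 303 fell at 6 h (435 and 474 by DESeq2), of 10476 tested. Among the deeper libraries with the inhibitor, GBP5 (2.03 ± 0.54), GBP1 (1.73 ± 0.55), PSMB9 (0.60 ± 0.25) and TAP1 (0.59 ± 0.22) did not pass, and the total was 1 gene, or 6 with a replicate block, against 820. The total was 320 at 1 h without Control_1h replicate 3 and 522 at 6 h without Control_6h replicate 2.

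LPS at 1 h changed 1 gene in T cells (n = 4 against 4). IFIT2, an antiviral gene of the interferon response, had 110 ± 165 CPM against 12.3 ± 4.79, with a log2 change of 3.46 ± 0.62 and libraries that overlapped the controls. It was named because the count was 1, and it did not pass in 8 of 17 refits. Without adjustment 212 genes had p under 0.05, DESeq2 called 0, and the replicate block gave 3. The type I signature had 1 of 30 members past the test (9 adjusted over the list alone, adjusted p = 2e-09, and adjusted p = 0.0608 with an estimated correlation).

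At 6 h of LPS (n = 4 against 4), all 30 measured genes of the type I interferon signature rose in T cells (30 adjusted over the list alone, adjusted p = 6.41e-142). IFIT1, which binds foreign RNA, rose by 6.50 ± 0.63, from 14.4 ± 9.02 to 1354 ± 238 CPM. IFI6 rose by 5.35 ± 0.36, ISG15 by 4.93 ± 0.39 and MX1 by 4.68 ± 0.32 on the log2 scale. LAMP3, a lysosomal membrane protein, rose by 6.06 ± 0.52, and TNFSF10, the death ligand TRAIL, by 4.25 ± 0.48. Interferon gamma targets rose for 15 of 23 (18 adjusted over the list alone, adjusted p = 1.71e-22). Class I and antigen processing genes rose for 13 of 17 (15 adjusted over the list alone, adjusted p = 1.51e-17), and ribosome biogenesis genes for 13 of 28 (15 adjusted over the list alone, adjusted p = 2.07e-08). In all, 588 genes rose and 296 fell, and the total of 884 was 473 with donor 4 left out.

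**Figure D1:**
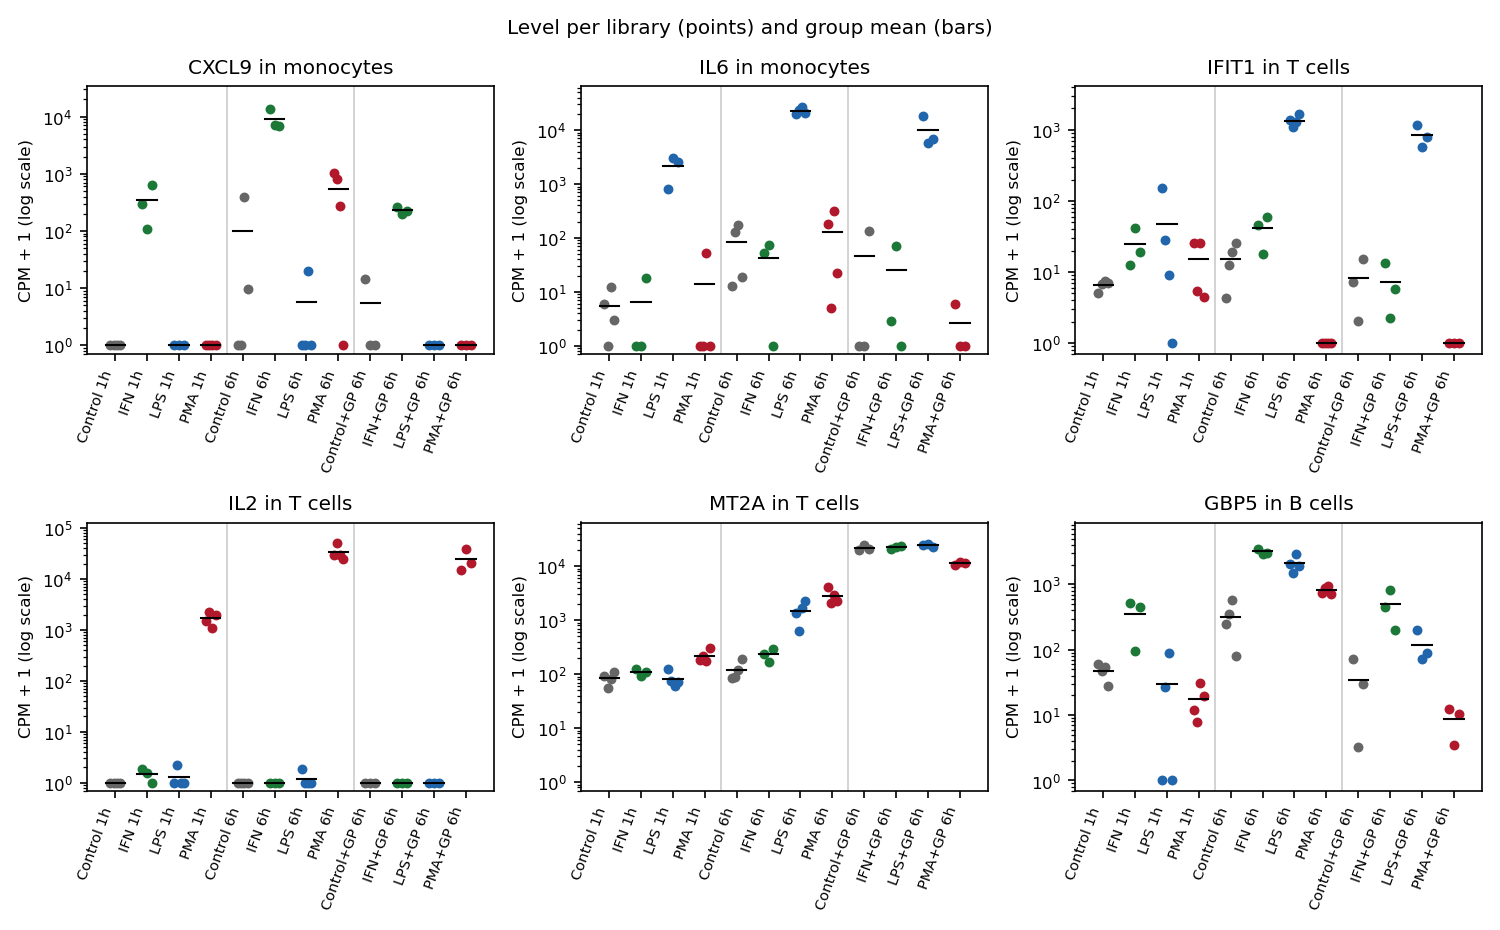
CPM plus 1 (log axis) of 6 genes in their cell class, by group, with a point per library and a bar at each group mean. Values here are scaled by totals over all genes of the class, so means differ slightly from the text. CXCL9 in monocytes ran from 6897 to 13740 CPM in IFN_6h and from 0 to 392.9 in Control_6h. IFIT1 in T cells ran from 1089 to 1654 in LPS_6h and from 3.376 to 24.3 in Control_6h. MT2A in T cells ran from 19780 to 24810 in ControlGolgiPlug_6h and from 84.4 to 189.9 in Control_6h.

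PMA/ionomycin at 1 h raised early activation genes in T cells (n = 4 against 4). IL2 was at least 1920-fold higher (1724 ± 512 CPM against no count). EGR3 rose by 8.70 ± 0.48, NR4A1 by 8.29 ± 0.60 and CD69, an early activation receptor, by 5.57 ± 0.40 on the log2 scale. IFNG rose by 6.69 ± 0.80 and TNF by 5.81 ± 0.53. Immediate early genes rose for 29 of 32 members (29 adjusted over the list alone, adjusted p = 7.88e-86), and NF-kB feedback genes for 15 of 22 (15 adjusted over the list alone, with 1 that fell; adjusted p = 2.04e-21). Lymphocyte cytokines rose for 19 of 25 and fell for 1 (21 and 2 adjusted over the list alone, adjusted p = 4.24e-21), or 17 of 21 without the genes that named clusters. Genes of quiescence and homing fell for 8 of 18 and rose for 2 (9 and 2 adjusted over the list alone, adjusted p = 2.61e-06), or 8 and 1 of 15 without the naming genes. TXNIP, a brake on glucose uptake, fell by 2.35 ± 0.23 and KLF2, a factor of resting T cells, by 1.44 ± 0.26. In all, 679 genes rose and 523 fell, and the total of 1202 was 776 with donor 4 left out.

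By 6 h of PMA/ionomycin (n = 4 against 4), 2662 genes were higher and 3038 lower in T cells. IL2 reached 33960 ± 12190 CPM against no count in the controls. IFNG rose by 10.88 ± 1.05 on the log2 scale, IL2RA, a subunit of the IL2 receptor, by 7.96 ± 0.72 and TNFRSF9, a costimulatory receptor, by 8.50 ± 0.56. Lymphocyte cytokines rose for 22 of 25 and fell for 2 (22 and 2 adjusted over the list alone, adjusted p = 1.02e-07, and adjusted p = 0.0929 with an estimated correlation), or 20 of 21 without the naming genes. Activation receptors rose for 17 of 19 (17 adjusted over the list alone, adjusted p = 1.06e-12), or 13 of 15 without them. Growth genes rose together: 27 of 28 of ribosome biogenesis and MYC targets (28 adjusted over the list alone, adjusted p = 1.29e-32), with NOP16, a nucleolar protein, at 3.87 ± 0.34 and SRM, spermidine synthase, at 3.64 ± 0.27. Genes of endoplasmic reticulum stress rose for 25 of 28 and fell for 1 (25 and 1 adjusted over the list alone, adjusted p = 8.75e-10), and glycolysis genes for 18 of 23, while 1 fell (18 and 1 adjusted over the list alone, adjusted p = 1.67e-06), with LDHA, lactate dehydrogenase, at 2.32 ± 0.26. KLF2 fell by 7.86 ± 0.45 and CCR7, a lymph node homing receptor, by 1.66 ± 0.20. Quiescence and homing genes fell for 12 of 18 and rose for 3 (12 and 3 adjusted over the list alone, adjusted p = 6.56e-09), or 9 and 3 of 15 without the naming genes. The type I interferon signature was lower for 23 of 30 (23 adjusted over the list alone, adjusted p = 2.6e-07, and adjusted p = 0.111 with an estimated correlation), with MX1 down by -3.63 ± 0.40.

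The T cell responses to PMA/ionomycin at 6 h and 1 h differed for 4038 genes, 1897 higher and 2141 lower at 6 h (n = 4 in each of 4 groups). The response of SRM was higher by 3.93 ± 0.37, of HSPA5, a chaperone of the endoplasmic reticulum, by 3.11 ± 0.36 and of ENO1, a glycolytic enzyme, by 2.92 ± 0.20 on the log2 scale. ZFP36, which degrades cytokine messages, had a response lower at 6 h by -2.80 ± 0.25. Ribosome biogenesis genes were higher for 27 of 28 (27 adjusted over the list alone, adjusted p = 8.54e-30), and stress genes of the endoplasmic reticulum for 21 of 28 and lower for 3 (22 and 3 adjusted over the list alone, adjusted p = 4.5e-07).

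In NK and cytotoxic T cells at 6 h, LPS raised all 30 genes of the type I signature (n = 4 against 4; 30 adjusted over the list alone, adjusted p = 2.3e-117). IFIT1 and OAS3, antiviral sensors, rose by 5.50 ± 0.68 and 5.50 ± 0.52, and CD69 by 2.59 ± 0.39. Interferon gamma targets rose for 10 of 22 (15 adjusted over the list alone, adjusted p = 2.85e-22). PMA/ionomycin raised lymphocyte cytokines for 19 of 21 with 1 that fell (19 and 1 adjusted over the list alone, adjusted p = 3.04e-22), or 17 of 17 without the naming genes. IFNG rose by 11.24 ± 1.12, from 14.2 ± 5.25 to 34510 ± 12350 CPM, and CCL3 by 9.70 ± 0.71. CSF2, a growth factor of myeloid cells, was at least 1912-fold higher, GZMB, the granule protease granzyme B, rose by 3.24 ± 0.32, and CLIC3, a chloride channel protein, was at least 46.1-fold lower. Activation receptors rose for 16 of 20 (17 adjusted over the list alone, adjusted p = 1.12e-13), or 12 of 16 without the naming genes, and ribosome biogenesis genes for 26 of 27 (27 adjusted over the list alone, adjusted p = 3.28e-20). The totals were 219 up and 40 down for LPS and 1106 up and 1245 down for PMA/ionomycin, of 8064 tested. With interferon gamma (n = 3 against 4) 66 genes rose and 33 fell (49 and 53 with RLE factors), 152 in all with a replicate block. The total of 99 was 21, 36 and 41 without IFN_6h replicates 1, 2 and 3, and 39 and 47 without Control_6h replicates 2 and 3. Of its targets 1 of 22 passed (3 adjusted over the list alone, adjusted p = 0.000488, and adjusted p = 0.0741 with an estimated correlation). That gene, CXCL9, was at least 14.5-fold higher and did not pass in 9 of 14 refits. It stood at 87.5 ± 43.9 CPM, beside 9555 ± 3989 CPM in monocytes of the same group, and RNA from other cells was not tested for it. Among the deeper libraries with the inhibitor, edgeR called 0 genes, with 384 at an unadjusted p under 0.05 and 0 by DESeq2.

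In B cells LPS at 6 h (n = 4 against 4) raised 29 of 30 type I signature genes (30 adjusted over the list alone, adjusted p = 1.7e-120). IFIT1 rose by 5.81 ± 0.59, MX1 by 4.90 ± 0.66 and CXCL10 by 6.08 ± 0.98 to 3978 ± 1081 CPM, beside 680 ± 578 CPM in monocytes of the same group, and RSAD2, the antiviral enzyme viperin, was at least 86-fold higher. Interferon gamma targets rose for 12 of 24 (17 adjusted over the list alone, adjusted p = 7.03e-23). Under PMA/ionomycin, B cell activation genes rose for 15 of 20 (16 adjusted over the list alone, adjusted p = 3.8e-14), including TNF by 6.56 ± 0.87, CD69 by 3.54 ± 0.46 and MYC by 2.91 ± 0.69. IL6 was at least 222-fold higher, and ribosome biogenesis genes rose for 23 of 27 (25 adjusted over the list alone, adjusted p = 3.11e-17). B cell identity genes fell for 8 of 12 and rose for 1 (10 and 2 adjusted over the list alone, adjusted p = 2.83e-08), or 1 and 1 of 3 without the naming genes. Interferon gamma (n = 3 against 4) raised 9 of 24 targets (17 adjusted over the list alone, adjusted p = 3.64e-17), with GBP5 at 3.33 ± 0.53 and GBP1 at 2.87 ± 0.59. The totals were 132 up and 12 down for LPS, 516 and 588 for PMA/ionomycin, and 52 and 24 for interferon gamma (58 and 64 by DESeq2), of 6069 tested. With the inhibitor on both sides, interferon gamma changed 13 genes, and 5 of 24 targets rose (13 adjusted over the list alone, adjusted p = 2.29e-15), with GBP5 at 4.29 ± 0.68. The LPS total of 144 was 75 with donor 4 left out, the interferon gamma total of 76 was 22 without Control_6h replicate 2, and GBP5 in the deeper libraries did not pass when only these groups were modelled.

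The Golgi inhibitor alone raised metallothioneins, which bind zinc and copper, in monocytes and T cells (n = 3 against 4). All 8 rose in T cells (8 adjusted over the list alone, adjusted p = 2.52e-77) and all 8 in monocytes (8 adjusted over the list alone, adjusted p = 2.56e-22). MT2A reached 21920 ± 2660 CPM in T cells against 122 ± 48.8, a log2 change of 7.48 ± 0.33, and rose by 4.91 ± 0.57 in monocytes. MT1G was at least 1766-fold higher in T cells and 425-fold in monocytes, and HMOX1, heme oxygenase, at least 103-fold in T cells. Stress genes of the endoplasmic reticulum rose for 18 of 28 members in T cells, while 1 fell (23 and 1 adjusted over the list alone, adjusted p = 2.82e-17), and for 17 of 27 in monocytes (21 adjusted over the list alone, adjusted p = 1.23e-19). HSPA5 rose by 2.12 ± 0.28 and XBP1, a transcription factor of the unfolded protein response, by 1.82 ± 0.21 in T cells, and DDIT3, a stress transcription factor, by 2.99 ± 0.56 in monocytes. Genes of transport from the endoplasmic reticulum to the Golgi rose for 14 of 30 in T cells, while 1 fell (20 and 1 adjusted over the list alone, adjusted p = 1.29e-12), and for 16 of 30 in monocytes (20 adjusted over the list alone, adjusted p = 2.42e-16). KDELR2, which returns escaped proteins, rose by 1.77 ± 0.23 and 2.59 ± 0.44.

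In monocytes interferon genes were lower with the inhibitor than in the 6 h control. This comparison spans the gap in depth, which was not tested for these lists. The type I signature fell for 22 of 30 (25 adjusted over the list alone, adjusted p = 7.78e-23), and interferon gamma targets for 19 of 31 (25 adjusted over the list alone, adjusted p = 8.23e-17). CXCL10 was at least 157-fold lower, and GBP1 was lower by 4.10 ± 0.81, at 54.3 ± 53 CPM against 989 ± 456. The 1 h control held GBP1 at 64.4 ± 26.1 CPM, so its level with the inhibitor was near that at 1 h. In T cells the type I signature fell for 10 of 30 (13 adjusted over the list alone, adjusted p = 2.06e-07, and adjusted p = 0.104 with an estimated correlation). In all, 258 genes rose and 259 fell in monocytes (256 and 524 by DESeq2), and 807 rose and 457 fell in T cells (643 and 717 by DESeq2). The monocyte total of 517 was 254, and the T cell total of 1264 was 803, without ControlGolgiPlug_6h replicate 3.

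**Figure D2:**
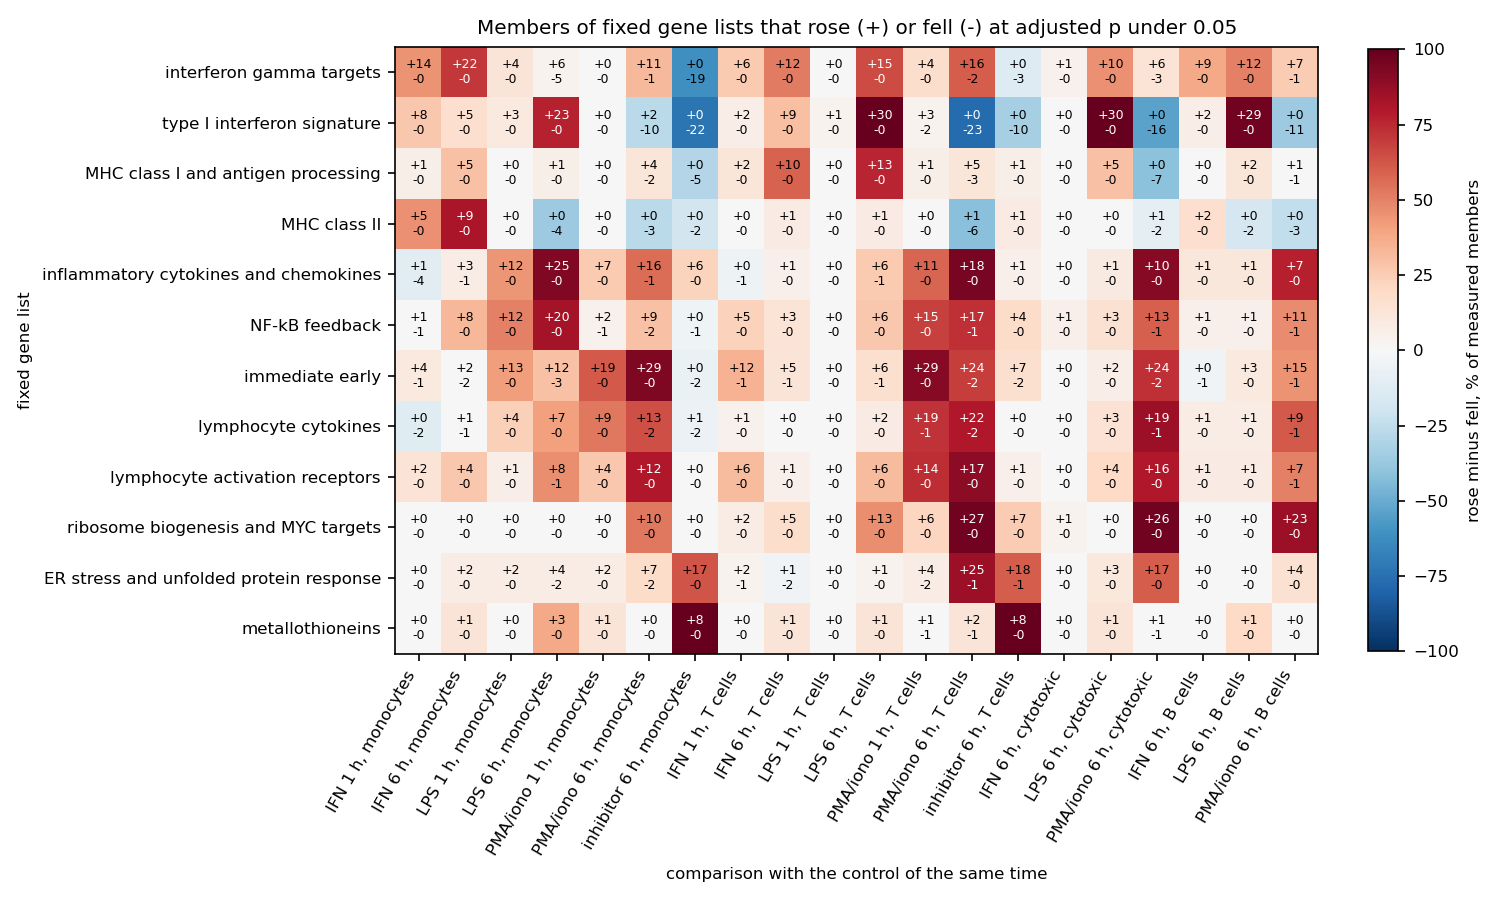
Members of 12 gene lists that rose (+) or fell (−) in 20 comparisons with a control, with colour for the difference as a percent of measured members. The type I interferon signature under LPS at 6 h had 30 of 30 members up in T cells, and metallothioneins under the inhibitor alone 8 of 8 in monocytes and in T cells.

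The responses to stimuli were then compared with and without the inhibitor, by the test of the difference. In T cells the response to PMA/ionomycin differed for 587 genes, 300 higher and 287 lower with the inhibitor (n = 3, 3, 4 and 4). Metallothioneins were lower for 4 of 8 members (6 adjusted over the list alone, adjusted p = 1.77e-09), with MT2A at -5.48 ± 0.40. Interferon gamma targets were lower for 8 of 23 (11 adjusted over the list alone, with 1 higher; adjusted p = 6.39e-09), with GBP5 at -5.58 ± 0.79 and IRF1 at -2.63 ± 0.42. Class I and antigen processing genes were lower for 5 of 17 (5 adjusted over the list alone, adjusted p = 4.37e-07), with PSMB9 at -3.07 ± 0.37 and TAP1 at -2.44 ± 0.29. The response to LPS in T cells differed for 1 gene, MT2A at -3.44 ± 0.39 (18 genes with a replicate block). MT2A stood at 21920 ± 2660 CPM with the inhibitor alone and at 122 ± 48.8 in the plain control. Its differences under PMA/ionomycin and LPS therefore start from unlike levels. After LPS with the inhibitor it stood at 24270 ± 1592 CPM. In monocytes the LPS response differed for 63 genes. HERPUD1, which acts in disposal of misfolded proteins, was higher with the inhibitor by 3.37 ± 0.76, and the chemokine CCL2 lower by -6.46 ± 1.33. Class II genes were higher for 4 of 11 (10 adjusted over the list alone, adjusted p = 4.95e-13), and inflammatory genes lower for 5 of 27 (8 adjusted over the list alone, adjusted p = 4.34e-08). HLA-DPA1 and HLA-DPB1, among the 4, did not pass without LPSGolgiPlug_6h replicate 3. HLA-DPA1 also started from unlike levels, at 993 ± 532 CPM in the plain control and 355 ± 247 CPM with the inhibitor alone. After LPS it stood at 136 ± 82.6 CPM without and 762 ± 711 CPM with the inhibitor. With the inhibitor its LPS and control libraries overlapped. The response to interferon gamma in monocytes differed for 23 genes, among them CDKN1A, a cell cycle inhibitor, at -3.32 ± 0.56, and for 2 genes without Control_6h replicate 2. Of the groups in this test only Control_6h was shallow, with medians of 763 to 1519.5 counts per cell. The gap in depth therefore does not cancel in it. None of 31 targets passed in that test (3 lower adjusted over the list alone, adjusted p = 0.000248, and adjusted p = 0.272 with an estimated correlation).

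The share of monocytes among cells was compared with the control of the same time by exact two-sided permutation tests. It was 24.4 ± 4.80% (SD, n = 4) in controls at 1 h, 4.00 ± 1.38% after LPS (n = 4, exact p = 0.0286, adjusted 0.0856) and 4.70 ± 2.57% after PMA/ionomycin (n = 4, exact p = 0.0286, adjusted 0.0856). After interferon gamma at 1 h it was 9.28 ± 3.56% (n = 3, exact p = 0.0571). At 6 h the control share was 15.4 ± 7.48% (n = 4), with 6.14 ± 2.22% after LPS (n = 4, exact p = 0.0571), 12.3 ± 3.80% after PMA/ionomycin (n = 4, exact p = 0.571) and 23.3 ± 15.1% after interferon gamma (n = 3, exact p = 0.457). The smallest p either design allows is 0.0286, and no share passed after adjustment over the 6 tests. A paired sign-flip test over replicates gave exact p = 0.125 for LPS and for PMA/ionomycin at 1 h, the smallest that 4 pairs allow.

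**Figure D3:**
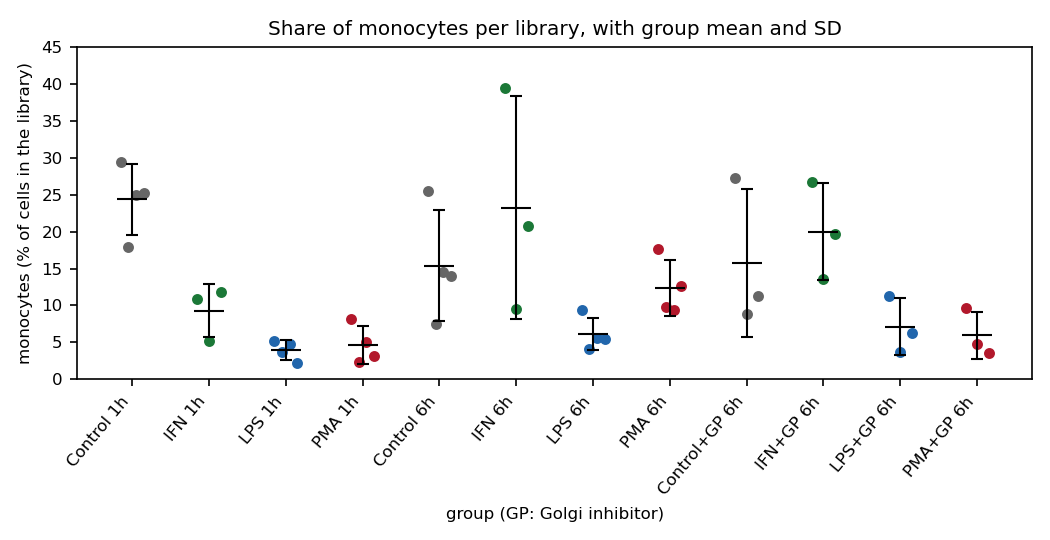
Monocytes as a percent of cells in each library of the 12 groups (points), with the group mean and SD. The 4 libraries of LPS at 1 h averaged 4.00% and those of the 1 h control 24.4%.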

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

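All tests of explanations and all splits of libraries in this part were chosen after the results were seen. In 48 checks of a library measure within a group of 4, 3 values, from 2 libraries, stood far from the others, and chance does so in about 1 of 20 groups. The median in Control_1h replicate 1 was 2559 counts per cell, against 1174 to 1305.5 in the other 3 libraries. At an equal 1000 counts its median was 603 genes per cell, against 619 to 622. NK and cytotoxic T cells made up 18.2% of PMA_1h replicate 2, against 8.74% to 9.25%. Both libraries follow their donor number. Replicate 1 had the highest median counts per cell in each group of 4, such as 2999 in LPS_6h. Replicate 2 had the highest share of NK and cytotoxic T cells in every group but LPS_6h and LPSGolgiPlug_6h, such as 26.4% in Control_6h.

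Responses differed between conditions, by tests of the difference, for 63 genes (LPS with and without the inhibitor, monocytes), 23 (interferon gamma with and without it, monocytes), 1 and 587 (LPS and PMA/ionomycin with and without it, T cells), 260 (LPS at 6 h and 1 h, monocytes) and 4038 (PMA/ionomycin at 6 h and 1 h, T cells). Splits that shuffled stimulus labels within each arm were run first. There 6 of 40 draws reached the 63 genes (highest other 738), 2 the 23 (55), 11 the 1 gene (153) and 5 the 587 (5347), so chance was not excluded for these. The real split was the 1 of 40 that reached the 260 (highest other 2) and the 4038 (highest other 4032). Draws with several times the real count show a structure of the samples, since shuffling 1 arm turns a difference of effects into their sum, so these draws do not exclude chance for the 4038 either. In exchanges of whole donor pairs, chosen after that, the real split alone reached the 63 (highest other 9), 587 (96), 260 (30) and 4038 genes (1). The 1 gene was reached in 2 of 35 splits (highest other 1). Each other exchange mixes libraries with and without the inhibitor, or of both times, within a group. The effects of inhibitor or time then widen the spread within groups and lower the counts, so this scheme does not exclude chance either. For the 23 genes the 10 exchanges are too few (highest other 0).

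Clusters left without a cell class held a larger share of every library than in any library of the matching control in 3 groups. The mean was 4.40% in IFN_6h and 5.95% in PMA_6h, against 1.07% in the 6 h control, and 7.48% in PMAGolgiPlug_6h, against 2.47% in the inhibitor control. These clusters led with dendritic cell, platelet or mixed genes, and 1 library of LPSGolgiPlug_6h held 31.5% of cells in them.

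Interferon gamma was compared with the control across a gap in depth, and so was the inhibitor alone. Of the 605 genes called in T cells at 1 h of interferon gamma outside its lists, 77.9% had the same sign in the inhibitor control against the 6 h control, which hold no interferon gamma (471 genes, 95% exact interval 74.3 to 81.1). For PMA/ionomycin calls at 1 h the figure was 58.5%. Within the deeper libraries, where interferon gamma was given for 6 h with the inhibitor, 56.9% of the 605 genes had the same sign (52.8 to 60.8). The PMA/ionomycin figure comes from other genes and another comparison, so it sets no baseline for this share. The intervals treat genes as independent, so they do not measure the spread between libraries. For the 605 genes a difference between library sets and a response to interferon gamma cannot be told apart. The targets of interferon gamma in monocytes argue against the library set as their cause, with a median log2 change of 1.37 within the deeper libraries and 24 of 31 members over 0 (p = 0.000567, camera with an estimated correlation). A biological source for the other genes was not tested.

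For the inhibitor alone in T cells, the gap in depth was set against interferon gamma at 6 h, which spans it without the inhibitor. Metallothioneins had a median log2 change of 0.216 there against 8.66 with the inhibitor (7.71 with genes absent from the controls at their bound), and all 8 members lay lower, the 5 with an error in both by over 2 SE. Genes of endoplasmic reticulum stress had a median of 0.036 against 1.16, with 27 of 28 members lower. These values argue against depth as the whole cause of either rise. A response to blocked transport may account for them as a hypothesis, while other differences between these cultures were not tested.

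Transcripts of T cell cytokines in the monocyte class after PMA/ionomycin at 6 h might come from free RNA or doublets. If cells of the T cell class were the source, their markers would appear at the same fraction of the T cell level. That class leaves out the cytotoxic T cells, which were merged with NK cells. The highest of 8 markers reached 19.4%, and 4 of 5 cytokines lay above it, with a median of 40.2% and IL2 below at 6.85%. Among them XCL1 and XCL2 stood at 287% and 195% of the T cell level. For the 4 above the markers this argues against the T cell class as the only source, but it cannot exclude cytotoxic T cells. Against all lymphocytes pooled, a test added after that result, 2 of 5 lay above the highest marker (21.0%), with cytokines at 9.09% to 29.2%. These 2 were XCL1 at 29.2% and IFNG at 21.9%, the latter close to that marker. Free RNA of lymphocytes together and expression in monocytes therefore cannot be told apart for the cytokines within the marker range.

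All 35 splits of the libraries were fitted for each count against a control. For every planned count against a control except LPS at 1 h in T cells, the real split alone called as many genes. For LPS at 1 h in T cells 3 splits did (real 1, highest other 1). Most of these splits do not respect the donor, and their shares were not adjusted over the counts, so they do not exclude chance. In monocytes the real count and the highest other were 218 and 13 for interferon gamma at 1 h, 405 and 145 at 6 h, 107 and 57 for LPS at 1 h, 966 and 15 at 6 h, 122 and 5 for PMA/ionomycin at 1 h, 1688 and 88 at 6 h, and 517 and 210 for the inhibitor. In T cells they were 615 and 210 for interferon gamma at 1 h, 820 and 412 at 6 h, 884 and 10 for LPS at 6 h, 1202 and 35 for PMA/ionomycin at 1 h, 5700 and 715 at 6 h, and 1264 and 718 for the inhibitor. For interferon gamma, LPS and PMA/ionomycin they were 99 and 45, 259 and 4, and 2351 and 65 in NK and cytotoxic T cells, and 76 and 25, 144 and 2, and 1104 and 79 in B cells. Among the added counts the real split also stood alone for the 2 controls, with 418 and 1 in monocytes and 1335 and 2 in T cells. The 10 splits among inhibitor libraries are too few, with 23 and 1 for interferon gamma and 891 and 28 for LPS in monocytes. In T cells they gave 1 and 0 for interferon gamma, 214 and 2 for LPS and 5662 and 4 for PMA/ionomycin. In B cells interferon gamma gave 13 and 2, and in NK and cytotoxic T cells 0 and 2, where all 10 splits called as many.

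Of the 35 splits, 8 put the 2 libraries of each shared donor on opposite sides, as the real one does, while the others leave both libraries of some donor together. The highest other count among these 8 was 9 for interferon gamma at 1 h and 74 at 6 h in monocytes, 33 and 111 in T cells, 37 and 354 for the inhibitor in monocytes and T cells, 35 for LPS at 1 h in monocytes and 243 for PMA/ionomycin at 6 h in T cells. Every real count was higher than all others of its 8, but 8 splits are too few for a share under 0.05.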

How the results depend on the processing

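Each count of genes was recomputed under every alternative that left enough libraries, and counts within 1.5 times the planned value are given here only as ranges. That held for 6 counts under all alternatives: LPS at 6 h (966, range 679 to 1092) and PMA/ionomycin at 6 h in monocytes (1688, 1165 to 2112), and in T cells PMA/ionomycin at 6 h (5700, 4604 to 5859), its difference between times (4038, 3129 to 4231), and LPS (214, 151 to 299) and PMA/ionomycin (5662, 4488 to 5879) among inhibitor libraries. Not run were at least 30 cells for LPS among inhibitor libraries and for the LPS difference in monocytes and for interferon gamma in B cells, and the fit without the 5% of cells with most counts for those 2 monocyte counts. LPSGolgiPlug_6h replicates 2 and 3 held 14 and 12 monocytes. Depth was not varied on its own. With simulated data 21.3% of 4-fold changes were recovered in monocytes and 71.1% in T cells, which held more counts and also differed in spread. The 9 added comparisons, the fits without the libraries in doubt, interferon gamma among inhibitor libraries in place of the planned comparison, clustering again, and the list tests with a replicate block and with RLE factors were chosen after seeing the data. Settings without donor 4, a library or cells hold fewer data by construction, and otherwise the cause was not tested. Values below are given with the planned value in parentheses.

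DESeq2 called 383 genes for interferon gamma at 1 h (218), 620 at 6 h (405), 42 among inhibitor libraries (23), 196 for PMA/ionomycin at 1 h (122) and 780 for the inhibitor alone (517) in monocytes. Its counts of differing responses there were 132 for LPS with the inhibitor (63), 86 for interferon gamma with it (23) and 435 for LPS between times (260). For T cells it gave 0 for LPS at 1 h (1), 4 for interferon gamma among inhibitor libraries (1) and 19 for the LPS response with the inhibitor (1). For interferon gamma it gave 176 in NK and cytotoxic T cells (99), 122 in B cells (76) and 41 in B cells among inhibitor libraries (13). With RLE factors the LPS response in T cells differed with the inhibitor for 2 genes (1).

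The split of a count into genes up and down depended on the size factors (RLE) or on the whole method (DESeq2) even where the total kept. PMA/ionomycin at 6 h in monocytes gave 694 up and 1231 down with RLE factors and 696 and 1416 by DESeq2 (974 and 714), and the median log2 change of all genes there was -0.54 with RLE (-0.07). Other splits are given beside their counts in the report.

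With at least 30 cells per library, counts were 623 for interferon gamma at 6 h (405), 36 among inhibitor libraries (23) and 41 for its difference with the inhibitor (23) in monocytes, and 238 for LPS (144) and 32 for interferon gamma among inhibitor libraries (13) in B cells. Without a filter they were 74 for interferon gamma among inhibitor libraries (23), 138 for the LPS difference (63) and 65 for the interferon gamma difference (23) in monocytes. In T cells they were 19 for LPS at 1 h (1), 30 for interferon gamma among inhibitor libraries (1) and 56 for the LPS difference (1). For interferon gamma in NK and cytotoxic T cells they were 152 (99) and, among inhibitor libraries, 4 (0), and in B cells there 56 (13). Without the 5% of cells with most counts, monocyte counts were 64 for LPS at 1 h (107), 139 for interferon gamma at 1 h (218), 112 for LPS between times (260) and 11 for interferon gamma with the inhibitor (23).

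With only the groups compared in the model, monocyte counts were 670 for interferon gamma at 1 h (218), 211 for LPS at 1 h (107), 229 for PMA/ionomycin at 1 h (122), 431 for LPS among inhibitor libraries (891), 775 between the controls (418) and 554 for LPS between times (260). In T cells interferon gamma among inhibitor libraries gave 3 (1) and the LPS difference 6 (1). In NK and cytotoxic T cells PMA/ionomycin gave 1304 (2351), and in B cells LPS gave 256 (144) and interferon gamma among inhibitor libraries 1 (13).

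With the replicate block LPS at 1 h gave 3 genes (1), interferon gamma among inhibitor libraries 6 (1) and the LPS difference 18 (1) in T cells, and interferon gamma 152 in NK and cytotoxic T cells (99). For monocyte shares after LPS (-20.4 points) and PMA/ionomycin at 1 h (-19.7) the block gave an exact sign-flip p of 0.125, the smallest that 4 pairs allow, in place of an unadjusted exact p of 0.0286. The block changed no other count by over 1.5 times and no call of a named gene. Without both libraries in doubt, LPS_1h replicate 4 and LPSGolgiPlug_6h replicate 1, the LPS difference in T cells was 10 (1). Interferon gamma among inhibitor libraries, in place of the planned comparison at 6 h, gave 23 genes in monocytes (405), 1 in T cells (820), 0 in NK and cytotoxic T cells (99) and 13 in B cells (76).

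Donor 4 left out of every group leaves 3 libraries at most per group. Monocyte counts were then 107 for interferon gamma at 1 h (218) and 238 at 6 h (405), 70 for PMA/ionomycin at 1 h (122), 317 for the inhibitor (517), 187 between the controls (418), 35 for LPS with the inhibitor (63), 7 for interferon gamma with it (23) and 144 for LPS between times (260). T cell counts were 387 for interferon gamma at 1 h (615) and 514 at 6 h (820), 0 for LPS at 1 h (1) and 473 at 6 h (884), 776 for PMA/ionomycin at 1 h (1202), 693 between the controls (1335) and 315 for PMA/ionomycin with the inhibitor (587). NK and cytotoxic T cells had 57 for interferon gamma (99) and 164 for LPS (259). B cells had 39 for interferon gamma (76), 7 among inhibitor libraries (13), 75 for LPS (144) and 605 for PMA/ionomycin (1104).

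Each library was left out in turn, with 1 library fewer in its group. In monocytes interferon gamma at 1 h (218) ran from 105 to 153, with 105, 120 and 117 without IFN_1h replicates 1, 2 and 3 and 118, 115 and 134 without Control_1h replicates 2, 3 and 4. At 6 h (405) it ran from 249 to 333, with 249 and 253 without IFN_6h replicates 1 and 2. Among inhibitor libraries (23) it ran from 8 to 35, with 35 and 8 without ControlGolgiPlug_6h replicates 1 and 2 and 13 without IFNGolgiPlug_6h replicate 3. The inhibitor alone (517) ran from 254 to 464, with 301 and 254 without ControlGolgiPlug_6h replicates 2 and 3. The controls (418) ran from 227 to 329, with 249 without Control_1h replicate 1 and 227 without Control_6h replicate 3. The LPS difference with the inhibitor (63) ran from 34 to 69, with 34 without LPSGolgiPlug_6h replicate 3. LPS between times (260) ran from 157 to 252, with 157 and 170 without LPS_1h replicates 2 and 3 and 173 without LPS_6h replicate 1. The interferon gamma difference (23) ran from 2 to 22, with 7, 2 and 7 without Control_6h replicates 1, 2 and 4, 9 and 5 without ControlGolgiPlug_6h replicates 2 and 3, 8 and 5 without IFN_6h replicates 1 and 3, and 10, 3 and 14 without IFNGolgiPlug_6h replicates 1, 2 and 3.

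In T cells interferon gamma at 1 h (615) ran from 320 to 581, with 390 and 320 without Control_1h replicates 2 and 3 and 358, 339 and 368 without IFN_1h replicates 1, 2 and 3. At 6 h (820) it ran from 522 to 721, with 522 and 527 without Control_6h replicates 2 and 3 and 535 without IFN_6h replicate 3. Among inhibitor libraries (1) it ran from 1 to 5, with 5 without IFNGolgiPlug_6h replicate 2. LPS at 1 h (1) ran from 0 to 2, with 0 without any replicate of Control_1h or LPS_1h replicate 1, and 2 without LPS_1h replicate 2 or 3. The controls (1335) ran from 799 to 1077, with 799 without Control_1h replicate 1, and the inhibitor alone (1264) from 803 to 1171, with 803 without ControlGolgiPlug_6h replicate 3. The LPS difference (1) ran from 1 to 7, with 2 without Control_6h replicate 1, 3 without LPS_6h replicate 2 and 7 without LPSGolgiPlug_6h replicate 1.

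For interferon gamma in NK and cytotoxic T cells (99) counts ran from 21 to 96, with 39 and 47 without Control_6h replicates 2 and 3 and 21, 36 and 41 without IFN_6h replicates 1, 2 and 3. Among inhibitor libraries (0) they ran from 0 to 1, with 1 without ControlGolgiPlug_6h replicate 3. In B cells (76) they ran from 22 to 60, with 22, 31 and 42 without Control_6h replicates 2, 3 and 4 and 24 without IFN_6h replicate 2. Among inhibitor libraries (13) they ran from 7 to 13, with 8 and 7 without ControlGolgiPlug_6h replicates 1 and 3 and 7 without IFNGolgiPlug_6h replicate 2.

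No share passed after adjustment with the planned settings, and p-values of shares here are unadjusted. The share of monocytes after interferon gamma at 1 h (-15.1 points, exact p = 0.0571) had an exact p of 0.0286 with the 4 named classes as denominator (-16.3), as log odds (-1.20) and after clustering again (-14.4). After LPS at 6 h (-9.25, exact p = 0.0571) it had an exact p of 0.0286 without Control_6h replicate 2 (-11.9, range -11.9 to -5.86). Within donors the share was lower than in the control in 3 of 3 after interferon gamma at 1 h and in 4 of 4 after LPS at 1 h, LPS at 6 h and PMA/ionomycin at 1 h. After interferon gamma at 6 h (7.87) the sign reversed without IFN_6h replicate 1 (-0.245, range -0.245 to 14.7), while the share was higher than in the same donor's control in 3 of 3 donors. The sign also reversed after PMA/ionomycin at 6 h (-3.08) without Control_6h replicate 1 (0.311, range -5.70 to 0.311), where it was lower in 3 of 4 donors. Clustering again gave 3.74 and -0.835 points for these 2 shares.

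Of 628 list tests 289 were called, and 115 with an estimated correlation. Fry called 277, of which 243 were shared, the replicate block 301, of which 288 were shared, and RLE factors 290, of which 283 were shared. Named genes made 143 pairs of gene and comparison with 2360 refits, of which 2322 kept direction and call, 38 lost the call and 0 reversed. For CXCL9 in NK and cytotoxic T cells (log2 change 7.65, range 5.75 to 7.95 over its refits) the comparison with the inhibitor on both sides gave no value, since neither group held a count.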

Other observations

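The comparisons in this part were added after the data were seen. With the inhibitor on both sides, LPS raised CCL20 in monocytes by 9.37 ± 1.10 on the log2 scale, IL6 by 7.89 ± 1.29 and ISG15 by 6.36 ± 0.89 (n = 3 against 3). Inflammatory cytokine genes rose for 18 of 27 members while 2 fell (19 and 2 adjusted over the list alone, adjusted p = 9.11e-14), NF-kB feedback genes rose for 17 of 24 (17 adjusted over the list alone, adjusted p = 2.6e-15), and the type I interferon signature for 28 of 30 (30 adjusted over the list alone, adjusted p = 1.84e-27). Monocyte identity genes fell for 15 of 24 (16 adjusted over the list alone, adjusted p = 7.57e-18), or 6 of 11 without the genes that named clusters. In T cells the type I signature rose for 30 of 30 (30 adjusted over the list alone, adjusted p = 6.89e-214), with IFIT1 at 6.87 ± 0.70 and MX1 at 5.39 ± 0.38. Interferon gamma targets rose there for 9 of 23 (15 adjusted over the list alone, adjusted p = 9.65e-17). In all, 440 genes rose and 451 fell in monocytes, and 186 rose and 28 fell in T cells.

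With the inhibitor on both sides, PMA/ionomycin raised all 28 ribosome biogenesis genes in T cells (28 adjusted over the list alone, adjusted p = 3.78e-29), and 2490 genes rose and 3172 fell (n = 3 against 3). All 8 metallothioneins fell (8 adjusted over the list alone, adjusted p = 2.72e-05), with MT2A at 11310 CPM against 21920 CPM and a log2 change of -0.96 ± 0.28. The controls themselves differed between 6 h and 1 h (n = 4 against 4). In T cells immediate early genes were lower at 6 h for 18 of 32 members (23 adjusted over the list alone, adjusted p = 1.02e-15), with FOSB at -4.92 ± 0.71 and DUSP1, a phosphatase, at -2.63 ± 0.38. In monocytes interferon gamma targets were higher at 6 h for 14 of 31 (22 adjusted over the list alone, adjusted p = 4.48e-14), with GBP1 at 3.90 ± 0.72. THBS1 was higher there by 4.00 ± 0.62. The totals were 151 up and 267 down in monocytes (223 and 180 with RLE factors) and 522 up and 813 down in T cells (733 and 534 with RLE factors). The monocyte total of 418 was 227 without Control_6h replicate 3 and 249 without Control_1h replicate 1, and the T cell total of 1335 was 799 without Control_1h replicate 1.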
